A study of Mus musculus with 6 samples.

How the data were processed

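The series holds 6 RNA sequencing libraries of mouse Lewis lung carcinoma cells in a stem-like state, 3 untreated (Control) and 3 treated with RT-MPs, all collected at 48 h. Per the labels' protocols, cells were grown in medium with 2% fetal bovine serum, total RNA was extracted with Trizol, and libraries were made with a stranded mRNA kit from KAPA. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10; the aligner version, the gene counter, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited FPKM values for 54446 genes per library, with Ensembl identifiers and symbols, and nothing else from their processing is stated.

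Groups were taken from the sample labels. Gene types, positions, lengths and GC content came from GENCODE M21 on mm10, which held 54409 of the identifiers; 93 symbols were shared by more than 1 identifier. Multiplying each FPKM by the summed exon length of the gene and by a library total gave whole reads, within 0.1 of a read, for 98.9% to 99.1% of the low values checked in each library. The totals at which this held best, 16949797 to 21877332 reads, are used as the depth. Reads summed over genes came to between 102.579% and 102.651% of these totals, so which reads the authors' totals count remains open. FPKM depends on the library's total, so reads taken by a few abundant genes lower all other values.

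Values were tested as log2(FPKM + 1) in genes with a mean FPKM of at least 1 over the 6 libraries (11915 genes). The pseudocount makes fold changes of low genes smaller than they were. RT-MPs was compared with Control by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend=TRUE), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; a second count asked also for an absolute log2 change of 1. All 6 libraries entered and no term for the replicate number was used. Fold changes and adjusted p-values of single genes come from this model. Means and SDs are of FPKM over the 3 libraries of a group.

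In total 38 gene lists were written from general knowledge before the data were examined, and the 34 with at least 5 tested members were compared with all other genes by limma's camera with an inter-gene correlation of 0.01, adjusted over lists. Counts of called members are given over all tested genes, and for part of the lists also adjusted over the list alone. A group of 3 against 3 allows no exact permutation p under 0.1, so no exact test is reported for single values.

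The rule for named genes was fixed before the data were examined. It took the 10 genes with the highest and the 10 with the lowest fold change among called genes with non-overlapping groups and a mean of at least 2 FPKM in the higher group, leaving out predicted gene names. It added up to 4 called members, in the list's direction, of each called list, up to 2 called members of each other list, the 5 most abundant called genes in each direction, and 25 genes whatever their result. Other genes are named only with a statement that they were chosen after their values were seen, or as controls of library quality or cell type.

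The fit was tested on simulated reads drawn from the Control means and the library totals over 11910 genes, with 100 genes changed at each fold. The changed genes were drawn from those with a Control mean of at least 5 FPKM, so recovery of lower genes was not simulated. With an even spread, 98% of genes changed 1.5-fold and 100% of genes changed 2-fold were recovered, and 12 unchanged genes were called. With 1 noisy library these were 58% and 89%, and 4 unchanged genes. Of 5 simulated lists shifted by 0.3 all 5 were called, and none of the others was. Noise was drawn separately for each gene, and the list simulation held no noisy library. It therefore cannot show how the list test behaves when a library deviates over many genes together.

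Alternatives chosen before the data were examined were other pseudocounts (0.1 and 5), no filter or a mean of at least 5 FPKM, median-ratio scaling, rescaling to a common sum (TPM), quantile normalization, the replicate number as a term, trend=FALSE, robust=TRUE, arrayWeights, ordinary least squares, leaving out each library, and for lists an estimated correlation, fry and ranks. Protein-coding genes only, and limma voom on the recovered reads, were added after the data were seen. Libraries were compared by correlation, principal components and a chi-square of recovered reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used to read the tables.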

Results

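Gene expression was measured by RNA sequencing in Lewis cells, a mouse lung carcinoma line, grown in a stem-like state. The cells were left untreated (Control, 3 libraries) or were treated with RT-MPs, a name the labels do not expand, for 48 h (3 libraries). Each library was deposited as one FPKM value (fragments per kilobase of gene, scaled to a read total that the sources used here do not define) for each of 54446 genes. The read totals that these values imply were 20710926, 18796729 and 19304715 in Control libraries 1 to 3 and 21877332, 18239102 and 16949797 in RT-MPs libraries 1 to 3. At this depth 100 reads in a gene of 2 kb correspond to between 2.29 and 2.95 FPKM. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples.

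RT-MPs replicate 3 stood apart from the other 5 libraries. Its FPKM values summed to 585752, against 296966 to 303798 in the others. A group of 9 genes labelled here as rRNA-like or short noncoding, among them Gm42418, Gm26917, Gm23935, Lars2 and Rn7sk, took 6.64% of its reads and 0.149% to 0.176% elsewhere. This group was chosen after its values were seen. Lars2 in it is annotated as protein-coding and had 888.3 FPKM in this library, against 17.4 and 16.9 in RT-MPs replicates 1 and 2. The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 took 0.175% of its reads, against at most 0.0548%. Its correlation with other libraries over log2(FPKM + 1) was between 0.959 and 0.969, whereas all other pairs lay between 0.984 and 0.993. The first principal component, with 59.0% of the variance, separated this library, and the second, with 19.9%, separated the controls from RT-MPs replicates 1 and 2. No pair of libraries agreed within sampling noise.

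**Figure D1:**
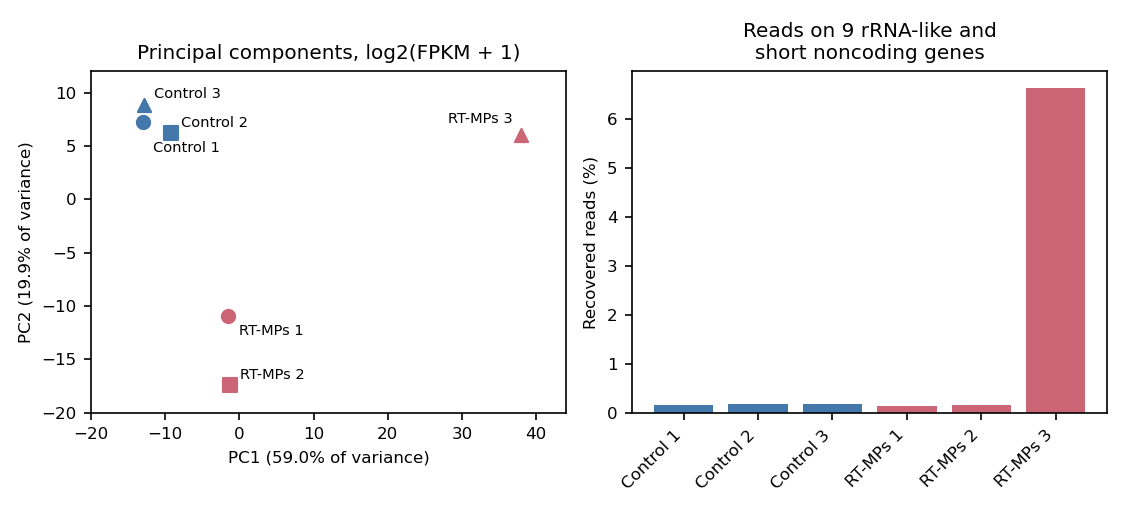
Left, the first and second principal components of log2(FPKM + 1) over the tested genes, each point a library (blue Control, red RT-MPs; circle, square and triangle for replicates 1, 2 and 3). Right, bars give the percent of recovered reads per library on 9 genes labelled rRNA-like and short noncoding, the protein-coding Lars2 among them. RT-MPs replicate 3 lies at 6.64% and the other libraries at 0.149% to 0.176%.

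The single comparison asks which transcripts differ between RT-MPs-treated and untreated stem-like cells. In treated cells, the lists of hypoxia and glycolysis genes and of NF-kB targets and inflammatory mediators were higher, while those of type I interferon response genes, integrated stress response targets and ribosome biogenesis genes were lower. These 5 lists passed the list test with its preset correlation and did not pass with an estimated correlation (adjusted p between 0.235 and 0.388). The gene with the highest fold among those named by rule was Sprr2e, a cornified envelope protein gene, at 7.68 ± 0.673 FPKM in Control and 26.3 ± 4.13 in RT-MPs (SD, n = 3 in each group). The neutrophil-attracting chemokine gene Cxcl2 rose 2.30-fold and the cytokine gene Lif rose 2.08-fold, while the interferon-stimulated genes Ifit3 and Ifit1 fell by 1.25 and 1.24 on the log2 scale. With limma, 476 of 11915 tested genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 154 were higher and 322 lower in RT-MPs, and 17 of them changed at least 2-fold (9 higher, 8 lower). The median absolute log2 change of the called genes was 0.47, a 1.39-fold difference. In all 476 called genes the 3 values of one group lay above the 3 of the other, and this held for 4763 of the 11915 tested genes, 39.97%. Chance gives 10% for a single gene, but genes are not independent, and a shift of whole libraries separates many genes together. The median log2 change of all tested genes was −0.09. In median-ratio scaling, the factor of every Control library was above that of every RT-MPs library. The share of separated genes therefore cannot show how widely the treatment acted. The count of called genes and the balance of directions depended on scaling: median-ratio scaling called 231 higher and 136 lower, quantile normalization 195 and 153, and rescaling to a common sum (TPM) 17 and 29, of which 14 were among the 476. The count depended on which library was left out: it was 0 without Control replicate 1, 2 without Control replicate 2, 0 without Control replicate 3, 74 without RT-MPs replicate 1, 10 without RT-MPs replicate 2 and 2548 without RT-MPs replicate 3, the last including all 476.

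**Figure D2:**
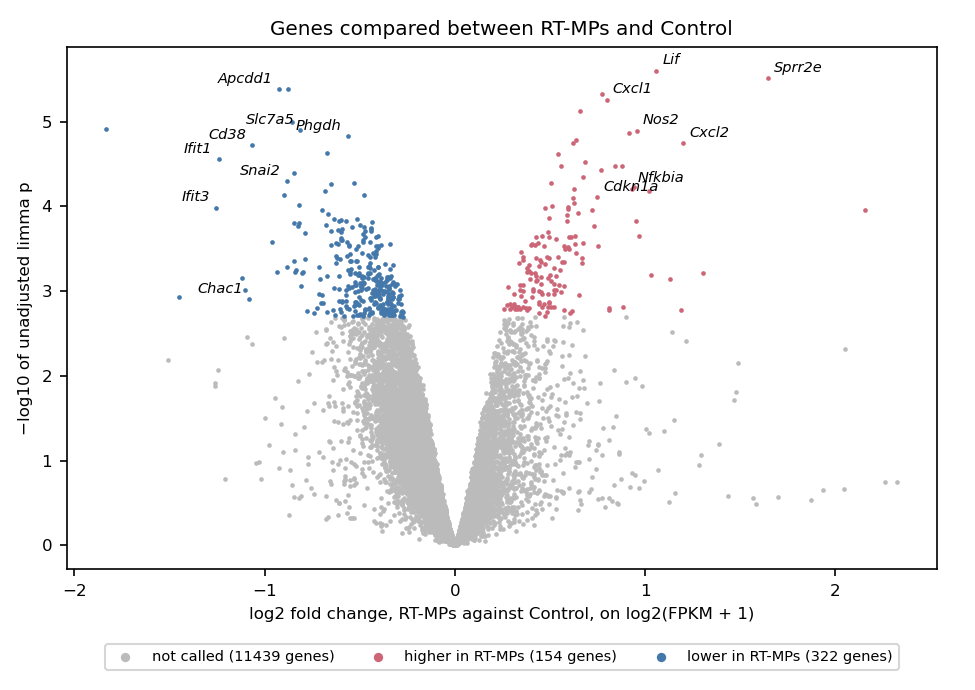
Log2 fold change of RT-MPs against Control on the log2(FPKM + 1) scale (x axis) and −log10 of the unadjusted limma p (y axis), one point per tested gene. The 154 genes called higher are red, the 322 called lower are blue and genes not called are grey; Sprr2e lies at 1.65 and Ifit1 at −1.24.

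The other genes with the highest and lowest fold changes among the called came from several functions. Among those that rose, Pgf, a growth factor of the VEGF family, went from 18.5 ± 2.80 to 38.4 ± 3.62 FPKM, and Nos2, the inducible nitric oxide synthase, from 85.8 ± 9.20 to 166.6 ± 4.25 FPKM. Gipr, the receptor of the incretin hormone GIP, rose 1.96-fold and Fam71f2 1.92-fold. Snord55, a small nucleolar RNA, rose 2.19-fold on a mean of 9.17 reads. Among those that fell, Cd38, an NAD-consuming surface enzyme, went from 11.2 ± 0.832 to 4.86 ± 0.663 FPKM, and Thbs1, a matrix glycoprotein, fell by 0.94 on the log2 scale. Snai2, a transcription factor of the epithelial-mesenchymal transition, fell by 0.88 (SE 0.10, adjusted p = 0.0207). The microRNA gene Mir874 fell by 1.45 on a mean of 2.5 reads, and Mir7669 was listed at 0 in RT-MPs libraries 1, 2 and 3; both lie at the floor of the depth. Among the most abundant called genes, the chemokine gene Cxcl1 rose from 471.7 ± 10.5 to 820.8 ± 35.2 FPKM, and the collagenase gene Mmp13 rose from 281.1 ± 9.32 to 368.5 ± 15.7 FPKM. The phagocytosis-related Anxa1 and the linker histone gene H1f0 fell by 0.33 and 0.32.

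Gene lists fixed before the data were examined were compared with all other genes by camera, and 15 of the 34 with at least 5 tested members passed an adjusted p of 0.05, 9 higher and 6 lower. None passed with an estimated inter-gene correlation, where the smallest adjusted p was 0.235. List medians are on the deposited scale. Rescaling each library to a common sum (TPM) moved the median of all tested genes from −0.09 to −0.38 and made the medians of the 9 lists called higher negative, and relative to that shift all 15 kept their sign. RT-MPs replicate 3 summed to 585752 FPKM, against 296966 to 303798 elsewhere, so this rescaling lowered its values relative to the other libraries. The short gene Gm23935 held 242123 FPKM of that sum, against 3516 ± 266 in Control. The cytosolic ribosomal protein list did not pass under quantile normalization (adjusted p = 0.235), and the mesenchymal and ER chaperone lists passed neither there (0.070 and 0.502) nor after rescaling to a common sum (0.131 and 0.224), where the NRF2 target, DNA replication and fatty acid oxidation lists did not pass either (0.10, 0.103 and 0.129). The lists of ROS-removing enzymes and of nuclear-encoded respiratory chain genes did not pass under these 2 scalings, with no filter, at a mean of at least 5 FPKM or with arrayWeights. Median and test had the same direction in the 15 called lists, whereas 13 of the 19 lists not called had a negative median and an upward difference from other genes.

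Hypoxia and glycolysis genes rose as a group. Of 34 tested members, 9 rose, none fell and 25 were not called, and 33 had a higher mean in RT-MPs; 14 rose when adjusted over the list alone. Slc2a1, the glucose transporter GLUT1 gene (chromosome 4, 119108711 to 119137983, mm10), went from 251.3 ± 24.4 to 393.3 ± 11.96 FPKM, a log2 change of 0.65 (SE 0.08, adjusted p = 0.0278). Ndrg1, a hypoxia-induced stress gene, rose 1.55-fold, the angiogenic factor gene Vegfa rose from 182.9 ± 15.4 to 272.5 ± 17.9 FPKM, and Ankrd37 rose 1.48-fold. Ero1l, the hypoxia-inducible oxidase of the endoplasmic reticulum, outside this list, was the most abundant gene called higher, at 568.4 ± 36.0 FPKM in Control and 851.7 ± 117 in RT-MPs. The list's median log2 change was 0.22 (camera adjusted p = 1.79e-17; adjusted p = 0.235 with an estimated correlation), and it was 0.24 without RT-MPs replicate 3.

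NF-kB target and inflammatory mediator genes also rose as a group, with 10 members higher, 2 lower and 22 not called among 34 (15 and 2 when adjusted over the list alone). Cxcl2 (chromosome 5, 90903871 to 90905938) went from 64.9 ± 0.684 to 151.7 ± 24.9 FPKM, 2.30-fold higher (SE of the log2 change 0.11, adjusted p = 0.0133). Lif (chromosome 11, 4257557 to 4272514) went from 14.04 ± 1.21 to 30.3 ± 0.901 FPKM, a log2 change of 1.06 (SE 0.07, adjusted p = 0.0109). Nfkbia, which encodes the NF-kB inhibitor I-kappa-B alpha, rose 1.90-fold, and the granulocyte growth factor gene Csf3 rose from 1.00 ± 0.406 to 2.46 ± 0.193 FPKM. The members that fell were Cxcl5 and Vcam1, at log2 changes of −0.77 and −0.62; both were picked after their values were seen. The list's median was 0.20 (camera adjusted p = 1.96e-13; adjusted p = 0.235 with an estimated correlation), and 0.19 without RT-MPs replicate 3. Immediate early genes had a median of 0.15 (adjusted p = 9.18e-04; adjusted p = 0.388 with an estimated correlation), with 2 members higher, 1 lower and 17 not called; the mean difference from other genes, 0.22, was 0.14 without RT-MPs replicate 3. Adjusted over the list alone, 7 immediate early genes were higher and 3 lower. Ier3, an early stress-response gene, rose from 356.0 ± 16.01 to 696.0 ± 124 FPKM, and the AP-1 subunit gene Fosl1 rose 1.47-fold.

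Type I interferon response genes fell as a group. All 44 tested members had a lower mean in RT-MPs, 18 fell by the test over all genes and 40 when adjusted over the list alone. Ifit1 (chromosome 19, 34640871 to 34650009) went from 17.4 ± 2.25 to 6.78 ± 0.929 FPKM, a log2 change of −1.24 (SE 0.12, adjusted p = 0.0166). Ifit3 went from 13.1 ± 1.24 to 4.99 ± 1.18 FPKM, a log2 change of −1.25 (SE 0.16, adjusted p = 0.0264). Ifit3b, a close paralog of Ifit3 with which it can share reads, fell by 0.96, and Cmpk2, a mitochondrial nucleotide kinase gene, fell by 0.84. The list's median was −0.45 (camera adjusted p = 1.27e-15; adjusted p = 0.235 with an estimated correlation), and −0.42 without RT-MPs replicate 3. The list of MHC class I presentation genes was not called (median −0.03, adjusted p = 0.60), with 1 of 21 members, the immunoproteasome subunit gene Psmb10, lower at −0.42. Adjusted over that list alone, 3 members were higher and 5 lower. Cd274, the PD-L1 gene, had a log2 change of −0.42 (SE 0.11, adjusted p = 0.0824) and was not called; without RT-MPs replicate 3 it was called, at −0.30 (adjusted p = 0.0229).

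**Figure D3:**
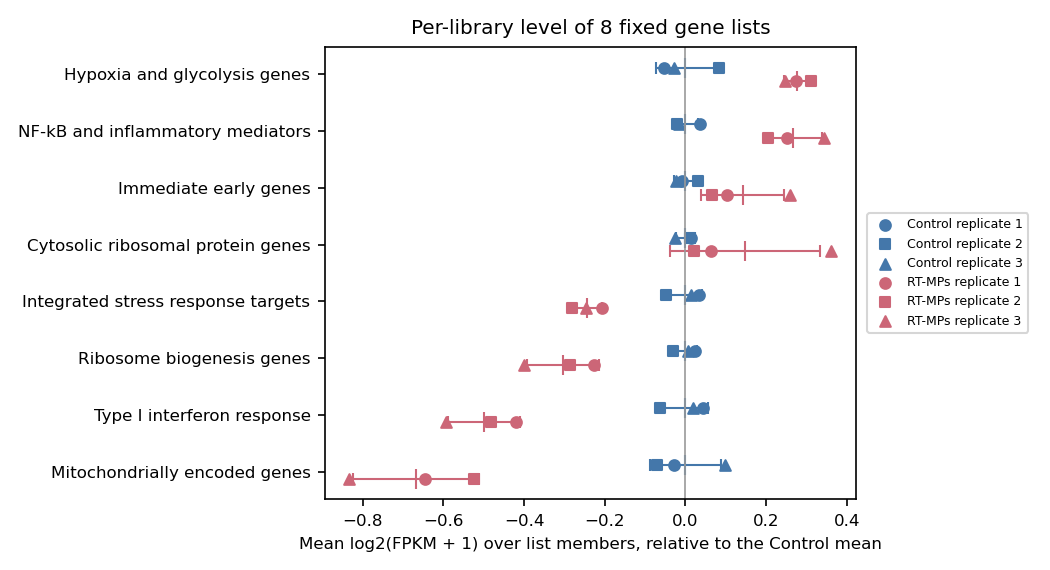
Mean log2(FPKM + 1) over the tested members of 8 fixed gene lists, relative to the Control mean (x axis); points are libraries (blue Control, red RT-MPs; circle, square and triangle for replicates 1, 2 and 3), and bars show the mean and SD of 3 libraries. On this scale the interferon list is lower by 0.50 and the hypoxia and glycolysis list higher by 0.28 in RT-MPs; rescaled to a common sum (TPM), the 4 lists drawn as higher have negative medians.

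Integrated stress response targets, many of them amino acid synthesis and uptake genes, fell as a group, with 9 of 31 members lower, 1 higher and 21 not called (20 lower and 3 higher when adjusted over the list alone). Slc7a5, the large neutral amino acid transporter gene, went from 70.2 ± 4.17 to 39.6 ± 2.34 FPKM, a log2 change of −0.81 (SE 0.07, adjusted p = 0.0133). Phgdh, the first enzyme of serine synthesis, went from 80.4 ± 1.76 to 54.1 ± 0.472 FPKM. The glutathione-degrading enzyme gene Chac1 fell by 1.08, and the neutral amino acid transporter gene Slc1a4 by 0.57. The median of the list was −0.28 (camera adjusted p = 4.70e-04; adjusted p = 0.388 with an estimated correlation), and −0.28 without RT-MPs replicate 3.

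Ribosome biogenesis genes fell as a group: all 33 members had a lower mean, 5 fell by the test over all genes and 21 when adjusted over the list alone. Bop1, Nop2, Rrp12 and Rrp9, which act in rRNA processing, fell by 0.46, 0.43, 0.42 and 0.41. The median was −0.33 (camera adjusted p = 2.35e-08; adjusted p = 0.354 with an estimated correlation) and −0.26 without RT-MPs replicate 3. None of the 51 cytosolic ribosomal protein genes was called, although 49 had a higher mean; their median was 0.15 (camera adjusted p = 1.30e-10; adjusted p = 0.573 with an estimated correlation) and 0.04 without RT-MPs replicate 3. Ribosomal protein genes picked by symbol, a wider set than these 51, took 9.51% of reads in RT-MPs replicate 3, against 7.46% to 7.92% elsewhere.

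Mitochondrially encoded transcripts fell as a group, with 5 of 13 members lower and 8 not called (11 lower when adjusted over the list alone), and 1 of the 13 had a higher mean. Together they took 2.00% to 2.14% of reads in Control and 1.81%, 1.72% and 1.44% in RT-MPs replicates 1, 2 and 3. This summed share fell less than the single members named below. The cytochrome b transcript mt-Cytb went from 1854 ± 149 to 1077 ± 127 FPKM, a log2 change of −0.79 (SE 0.11, adjusted p = 0.0293), and the complex I transcripts mt-Nd4 and mt-Nd2 fell by 0.83 and 0.60. mt-Co3 and mt-Atp6 fell by 0.88 and 0.85, and their low levels, 22.1 and 43.4 FPKM in Control, are uncertain because nuclear copies of mitochondrial DNA can take their reads. The median was −0.79 (camera adjusted p = 8.96e-06; adjusted p = 0.368 with an estimated correlation) and −0.69 without RT-MPs replicate 3. Nuclear-encoded respiratory chain genes had no called member among 60 and a median of 0.03 (adjusted p = 0.0295; adjusted p = 0.701 with an estimated correlation), which became −0.05 without RT-MPs replicate 3, where the list was not called; its mean difference from other genes, 0.10, was 0.18 without RT-MPs replicate 2.

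Genes of oxidative stress and iron-dependent cell death were called in both directions. Hmox1, the heme oxygenase gene (chromosome 8, 75093621 to 75100589), rose from 52.8 ± 4.41 to 76.2 ± 8.88 FPKM, a log2 change of 0.52 (SE 0.10, adjusted p = 0.0468). The NRF2 target list was called higher with a median of 0.03 (camera adjusted p = 0.00161, and 0.235 with an estimated correlation). Over all tested genes Hmox1 was its only member called higher, and 1 other of 27 was called lower. Adjusted over the list alone, 5 were higher and 1 lower. No ROS-removing enzyme gene was called among 23; the list passed camera (median 0.05, adjusted p = 0.0393; adjusted p = 0.571 with an estimated correlation) and did not pass without RT-MPs replicate 3 or without Control replicate 2, at adjusted p of 0.58 and 0.0572. The superoxide dismutase genes Sod1 and Sod2 had log2 changes of 0.02 (SE 0.06; −0.02 without RT-MPs replicate 3) and 0.13 (SE 0.06), the catalase gene Cat −0.22 (SE 0.07), the glutathione peroxidase genes Gpx1 and Gpx4 −0.04 (SE 0.09) and 0.00 (SE 0.11), and the quinone reductase gene Nqo1 0.15 (SE 0.12). With a library left out, Gpx1 lay between −0.12 (without RT-MPs replicate 3) and 0.03 (without RT-MPs replicate 2), and Nqo1 between 0.06 (without Control replicate 2) and 0.25 (without RT-MPs replicate 2). Sod2 was called with arrayWeights (adjusted p = 0.0189). Without RT-MPs replicate 3, Gpx4 was called at −0.13 and Cat at −0.18. Ferroptosis regulators were not called as a list (adjusted p = 0.42), with 5 members higher and 2 lower among 28 (5 higher and 6 lower when adjusted over the list alone). The iron transporter gene Slc11a2 rose 1.46-fold, while the cystine transporter gene Slc7a11 (−0.10, SE 0.15) and Acsl4 (−0.16, SE 0.18), which activates polyunsaturated fatty acids, were not called, and both had a value of 0.06 without RT-MPs replicate 3. Superoxide- and peroxide-producing enzymes were not called (adjusted p = 0.44), with Ero1l as the 1 called member of 11.

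**Figure D4:**
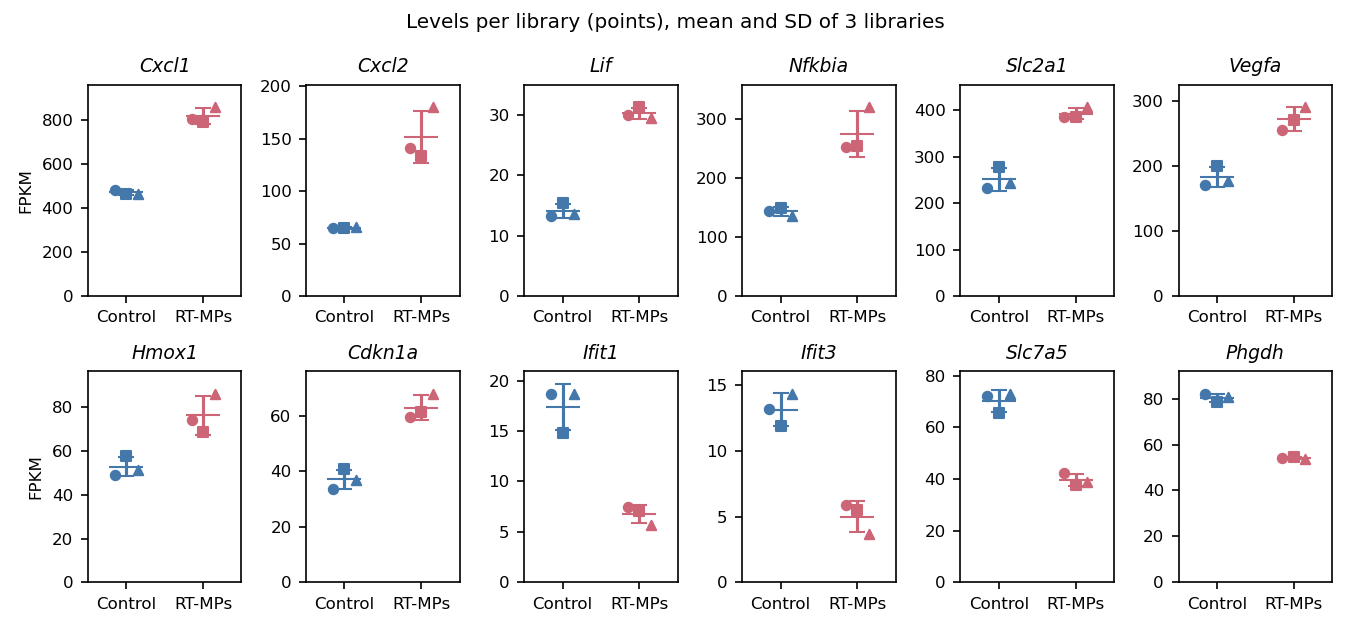
FPKM of 12 named genes (y axes, each starting at 0) in Control (blue) and RT-MPs (red); points are libraries (circle, square and triangle for replicates 1, 2 and 3), and bars show the mean and SD of 3 libraries. In each panel all 3 values of one group lie above the 3 of the other; Ifit1, Ifit3, Slc7a5 and Phgdh are lower and the other genes higher in RT-MPs.

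Of the cell cycle, DNA repair, p53 and apoptosis lists, only DNA replication passed the list test as run here, and others passed under some alternatives. Cdkn1a, the cyclin-dependent kinase inhibitor p21 gene, went from 37.1 ± 3.49 to 62.8 ± 4.48 FPKM, a log2 change of 0.75 (SE 0.09, adjusted p = 0.0235). It was the only member of the p53 target list called higher among 28, beside Sesn1, which fell by 0.41, and the list was not called (adjusted p = 0.44). Adjusted over the p53 list alone, 3 members were higher and 3 lower. Mdm2, at 0.18 (SE 0.10, adjusted p = 0.29), was not called, but was without RT-MPs replicate 3, at 0.29 (adjusted p = 0.0163). DNA replication genes had a median of −0.16 (camera adjusted p = 0.00490; adjusted p = 0.394 with an estimated correlation), with the replicative helicase subunit gene Mcm2 as the 1 called member of 43 and 11 lower, 1 higher when adjusted over the list alone. The mitotic list was not called (adjusted p = 0.071), although its kinase gene Aurkb rose 1.27-fold; it was called higher without RT-MPs replicate 3 (adjusted p = 5.56e-04), without Control replicate 1 (0.0392), under median-ratio scaling (0.0272), with arrayWeights (0.0018), with ranks (0.0483) and over protein-coding genes (0.0447). Mki67 had a log2 change of −0.15 (SE 0.20), and of 0.09 without RT-MPs replicate 3. The homologous recombination list was not called (adjusted p = 0.071), with Fancl lower at −0.45; it was called lower without RT-MPs replicate 2 (0.0136), without Control replicate 2 (0.0454), under median-ratio scaling (0.026), with no filter (0.0136) and with voom (0.0458), while its median of −0.18 became −0.10 without RT-MPs replicate 3 (adjusted p = 0.501). Of 31 apoptosis genes only the anti-apoptotic Mcl1 was called, at 0.32 (list adjusted p = 0.53, and 0.0387 by fry). Adjusted over the apoptosis list alone, 1 member was higher and 3 lower. Bax (0.09, SE 0.16, and −0.10 without RT-MPs replicate 3) and Bcl2 (−0.49, SE 0.11) were not called over all tested genes. Bcl2 was called without RT-MPs replicate 3, at −0.37 (adjusted p = 0.0151), and with voom (0.039).

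None of the 16 tested stemness markers was called, and the list was not called (adjusted p = 0.60). Myc (0.18, SE 0.07), Cd44 (−0.02, SE 0.10; 0.09 without RT-MPs replicate 3), Klf4 (−0.05, SE 0.16; −0.22 without RT-MPs replicate 3, and from −0.22 to 0.05 with a library left out) and Abcg2 (−0.12, SE 0.10; −0.05 without RT-MPs replicate 3) were not called, but Myc and Klf4 were with arrayWeights (adjusted p = 0.00602 and 0.0488). Sox2, Pou5f1, Nanog, Prom1 and Aldh1a1 had between 0 and 2 reads per library and were not tested, so a difference in them was not detectable at this depth. Mesenchymal genes were called higher as a list (median 0.09, adjusted p = 0.00344; adjusted p = 0.235 with an estimated correlation) with 3 members higher and 3 lower among 20: Cyr61 and Tgfb1 were among those that rose, by 0.84 and 0.39, while Thbs1 and Snai2 were among those that fell. Of 7 Wnt targets, the Wnt inhibitor genes Apcdd1 and Dkk2 fell by 0.92 and 0.82, and the list was not called (adjusted p = 0.39) except by fry (0.0252). Elf3, an epithelial transcription factor gene, rose 1.39-fold as the 1 called member of 5 in the epithelial list (adjusted p = 0.44). Notch and Hedgehog targets (adjusted p = 0.57) and collagens and matrix proteins (adjusted p = 0.24) had no called member, and the latter list was called higher without RT-MPs replicate 3 (adjusted p = 0.0167) and with arrayWeights (0.00789).

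Fatty acid oxidation genes fell as a list (median −0.17, adjusted p = 0.00161; adjusted p = 0.272 with an estimated correlation), with the carnitine shuttle genes Cpt1a and Slc25a20 lower by the test over all genes and 9 of 21 lower when adjusted over the list alone. ER chaperone genes had no called member among 29 and a median of 0.07 (adjusted p = 0.0118; adjusted p = 0.388 with an estimated correlation), and the list did not pass without RT-MPs replicate 1, at an adjusted p of 0.0828. Not called as lists were fatty acid synthesis (adjusted p = 0.83, Lpin1 higher and Fads1 lower), cholesterol biosynthesis (0.11, but called higher at a mean of at least 5 FPKM, 0.0293, and with arrayWeights, 0.0282), lysosome and autophagy (0.78, Gpnmb and Gusb lower), endocytosis (0.86), heat shock proteins (0.63, Fkbp4 lower), and metallothioneins and metal transport (0.13).

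Markers of other cell types differed in level. The leukocyte gene Ptprc did not exceed 0.006 FPKM and Adgre1, Csf1r and Tyrobp were listed at 0 in all 6 libraries, while Cd68, a lysosomal protein gene of macrophages and other cells, rose from 30.2 ± 2.41 to 39.3 ± 0.662 FPKM, and Cd14 and Itgb2 of the same list had 7.98 ± 0.776 and 6.31 ± 0.615 FPKM in Control. Among fibroblast markers Col3a1, Dcn, Pdgfra, Pdgfrb and Lum had 143.2, 38.6, 16.2, 5.94 and 5.86 FPKM in Control, while Col1a1 and Col1a2 did not exceed 0.0237 FPKM. The endothelial marker Eng had 13.8 FPKM and the lung epithelial markers Hopx and Abca3 had 10.4 and 6.78 FPKM in Control. The fibroblast list was not called (adjusted p = 0.27) except by fry (0.0276), with the matrix protein gene Dpt lower, from 91.6 ± 2.73 to 65.8 ± 4.32 FPKM, as the 1 called member of 6. Adjusted over the fibroblast list alone, 1 member was higher and 4 lower. Leukocyte, endothelial, lung epithelial and histone lists had 3, 2, 3 and 4 tested members, too few for the list test.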

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

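Protein-coding genes only and voom on recovered reads were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of the 20 alternatives for the count of 476 changed genes, it moved to 26 with no filter (24831 genes tested), 46 after rescaling to a common sum (TPM), 53 with ordinary least squares, 4576 with arrayWeights (which gave RT-MPs replicate 3 a weight of 0.08), 878 with protein-coding genes only and 801 with limma voom on recovered reads (455 of the 476 shared); it ran from 348 to 524 in the 7 others that kept all libraries without a block. Leaving out 1 library gave 0 (Control 1), 2 (Control 2), 0 (Control 3), 74 (RT-MPs 1), 10 (RT-MPs 2) and 2548 (RT-MPs 3); at the counts of 0, 1935 and 1839 genes had an unadjusted limma p under 0.05. The 17 genes of at least 2-fold became 28 with a pseudocount of 0.1, 3 with a pseudocount of 5, 3 with no filter, 11 at a mean of at least 5 FPKM, 46 after rescaling to a common sum (TPM), 41 with arrayWeights, 1 with ordinary least squares, 27 with voom and between 0 and 22 with a library left out. The 15 called lists became 8 after rescaling to a common sum (TPM) and 0 with camera's estimated correlation (13 lists with fry), and between 14 and 16 with a library left out. Among the 15, fry did not call cytosolic ribosomal protein genes (adjusted p = 0.363), ER chaperones (0.43) and immediate early genes (0.226). Nor did it call nuclear-encoded respiratory chain genes (0.968) and ROS-removing enzymes (0.696). Median-ratio scaling called 231 higher and 136 lower, and quantile normalization 195 and 153, against 154 and 322. Rescaling to a common sum divides the values of RT-MPs replicate 3 by a larger FPKM sum than in the other libraries. The causes of the other differences were not tested.

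Deviations from the group means correlated at 0.10, −0.08 and −0.03 between libraries of the same replicate number, and not every library correlated best with its own number. This check cannot show whether equal numbers were paired, because RT-MPs replicate 3 shaped the RT-MPs deviations. With Control replicate 1, for example, RT-MPs replicates 1 and 2 correlated at 0.0959 and 0.0595 and replicate 3 at −0.096. With the replicate block, limma called 0 genes and 0 genes at least 2-fold (2620 at an unadjusted p under 0.05), and all 34 lists kept their calls.

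Gpx4 (0.00, not called) turned to −0.12 with arrayWeights (adjusted p = 0.0348) and lay between −0.13 and 0.0715 with a library left out; its adjusted p ranged from 0.0348 to 0.992 over the alternatives. The mean difference of nuclear-encoded respiratory chain genes from other genes, 0.10, lay between −0.00505 and 0.18 with a library left out, lowest without RT-MPs replicate 3 (adjusted p = 0.30; range 4.69e-05 to 0.97). Apoptosis core genes, 0.018 relative to other genes, were lower by fry, which does not compare them with other genes (adjusted p = 0.0387; range 0.0387 to 0.92), as were Wnt targets (0.0252) and fibroblast markers (0.0276). Depth limits the genes with few reads, such as Mir874, Mir7669 and Snord55. With voom on recovered reads, Mir874 and Snord55 were not called (adjusted p = 0.0913 and 0.0916), and Mir7669 was (0.0435).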

Other observations

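The tests of noncoding reads, of length and GC content and of the GC trend were written before their results were seen; the other tests here, and the gene families, were chosen after. Small proline-rich protein genes, which encode cornified envelope proteins, lie together on chromosome 3. Of the 4 tested, Sprr2e, Sprr2h and Sprr1a rose (log2 changes 1.65, 0.92 and 0.60) and Sprr2d, at 1.14, was not called (adjusted p = 0.058) but was without RT-MPs replicate 3, at 0.88; the family median was positive under each scaling, between 1.028 and 1.16, and Sprr2 paralogs can share reads. The plasminogen activator gene Plat rose by 0.56, while Plau (0.17) and Plaur (0.19) were not called; without RT-MPs replicate 3 Plau was called, at 0.23. Tnfrsf9 rose from 186.4 ± 18.4 to 317.1 ± 5.02 FPKM as the 1 called member of 8 TNF receptor superfamily genes (median 0.07, 3 with a lower mean). Of 12 MMP and TIMP genes 1 rose (median 0.09), and of 18 Dusp phosphatase genes 1 fell (median −0.07).

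Interferon-inducible GTPase genes, some of them members of the interferon list, had a lower mean in all 10 tested and 6 fell, among them Irgm2 (−0.88) and Gbp7 (−0.79). All 20 cytosolic aminoacyl-tRNA synthetase genes had a lower mean and 2 of them, Wars (−0.42) and Gars (−0.32), fell. On this scale the median of all tested genes was itself −0.09, and Vars, Cars and Qars lay at only −0.01, −0.01 and −0.02. Of 18 amino acid transporter genes 16 had a lower mean and 3 fell, Slc7a5, Slc1a4 and Slc3a2. The 2 synthetases and 3 transporters that fell are members of the integrated stress response list. The medians of these families, −0.57, −0.24 and −0.20, were negative under each scaling, and relative to the all-gene median after rescaling to a common sum (TPM) they were −0.58, −0.17 and −0.12.

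The first pattern is that RT-MPs replicate 3 stood apart. Reads from rRNA-like and other noncoding genes alone do not account for it, since over 10290 protein-coding genes its mean correlation with replicates 1 and 2 was 0.982, against 0.996 to 0.997 in the other pairs within a group. Lars2 was still among these protein-coding genes. Fewer reads do not either, since a chi-square per gene that allows for read number was at least 134.5 against replicates 1 and 2, which differed from each other by 5.80. This chi-square included the rRNA-like genes, which add much to it. Its size therefore does not show how far a typical gene differed. A trend with transcript length and GC content removed 47.9% of the variance of its difference from replicates 1 and 2, but the SD stayed 1.60 times that of replicate 1 against 2, from 2.22 before. A difference in RNA quality or library preparation may remain, and no biological explanation was tested for a single library.

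The second pattern is the lower level of interferon-response genes. It did not come from replicate 3 alone, because the list's median was −0.42 without it, against −0.06 over all tested genes. Loss of leukocytes that carry Ptprc, Tyrobp, Fcer1g, Laptm5, Coro1a and Csf1r is argued against by the low level of these 6 transcripts. They were picked after the data were seen and summed to 0.571 FPKM in Control, 0.229% of the 250.0 FPKM the list lost. Cd68, Cd14 and Itgb2 of the leukocyte list were not among the 6 and were higher. They had 30.2, 7.98 and 6.31 FPKM in Control and 39.3, 8.47 and 5.78 in RT-MPs. A sum that includes them was not tested. A shared fall of immune genes is argued against by the NF-kB list, whose median was 0.20 against −0.09 over all tested genes, with no gene in common. An effect of RT-MPs on interferon signalling in these cells stays a hypothesis, raised and examined on the same data. Interferon signalling itself was not measured, and other differences between the 2 sets of cultures stay open.

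The third pattern is the lower level of mitochondrially encoded transcripts. Reads shared with nuclear copies are argued against by the 6 abundant transcripts, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Cytb and mt-Co1, whose median was −0.64 at 220.7 FPKM or more. The GC trend of nuclear genes predicted 15.5% of the median fall of 0.70, at a GC content of 37.1%, lower than that of all but 1.15% of nuclear genes. An even loss of mitochondrial mRNA is argued against by mt-Co1, at −0.16 (SE 0.10), which lay 0.51 above the median of 5 other abundant transcripts. The cause of the uneven fall was not tested, and capture of mitochondrial RNA by the library kit stays open.

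The hypothesis that glycolytic enzymes and transporters alone make up the rise of the hypoxia and glycolysis list was tested by splitting it. Pfkfb3, Pfkfb4 and Pdk1, which regulate glucose use, were not counted among these enzymes. The 16 tested members other than these enzymes and transporters had a median of 0.32, with 15 higher and 6 called. The 18 glycolytic enzymes and transporters had a median of 0.12, with 18 higher and 3 called. The rise may thus be wider than these enzymes and transporters. Whether it goes beyond glycolysis and its regulators was not tested, nor was its trigger.

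The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, gave 476 changed genes (highest other 1), 17 genes of at least 2-fold (highest other 1) and 15 called lists (highest other 13). For the interferon list the unadjusted camera p was 7.46e-17 in the real split and 3.09e-07 at the smallest in the others; for hypoxia and glycolysis these were 5.26e-19 and 5.20e-10. Of the 15 called lists, 4 had smaller p-values in other splits than in the real one: nuclear-encoded respiratory chain genes (4.25e-11 against 0.0121), cytosolic ribosomal protein genes (1.05e-20 against 1.53e-11), ROS-removing enzymes (1.33e-04 against 0.0173) and immediate early genes (4.22e-05 against 2.16e-04).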
